A study of Caenorhabditis elegans with 2 samples.

How the data were processed

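The data are transcription factor ChIP-seq of RNT-1, the RUNX protein of Caenorhabditis elegans, from whole hermaphrodite late embryos collected 5 h after synchronization by egg bleaching. Per the labels' protocols and sample notes, the worms carried RNT-1 with a C-terminal GFP and FLAG tag, chromatin was sheared by sonication, and the immunoprecipitation used an antibody against GFP. The antibody field of the labels reads rnt-1 instead, and the sample notes were followed here. The labels name 2 biological replicates with 1 library each and no second condition, so all samples formed 1 group and no contrast between conditions was made.

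The deposited files are lists of regions in narrowPeak format on the genome builds ce10 and ce11. There is 1 list per replicate that keeps background regions, 1 list called on both replicates together, and 1 shorter list thresholded by the irreproducible discovery rate (IDR), per the file descriptions that came with the samples. Those descriptions name a control alignment for every list. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The signal value of each region is a score that the authors deposited, with no stated scale. It was used to rank regions within a list, to correlate the replicates by rank and on log2 values, and to compare medians of peaks within a list. The deposited −log10 q-value was not used for ranking, because all 1931 IDR peaks on ce11 carry the same highest value of 2.07. The summit position is the offset that the authors deposited in the last column. Read depth is unknown from these files, and no interval that needs it is given. Intervals on shares of peaks or genes cover counting error only.

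All positions are 1-based on ce11 (WBcel235), and no ce11 region ended past a chromosome of that assembly. Genes, transcripts and their biotypes came from Ensembl release 115, with 19973 nuclear protein-coding genes and 29314 annotated start sites. Mitochondrial gene names came from a RefSeq gene table of the same assembly. The ce10 lists were compared with the ce11 lists by counts, and replicate overlap was also computed on the ce10 lists as an alternative. A gene was counted as bound when an IDR peak summit lay from 1000 bp upstream to 200 bp downstream of any of its annotated starts, so 1 summit can count for several genes.

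Replicates were compared by ranking each replicate's regions by signal, taking as many top regions as there are IDR peaks, and counting replicate 1 regions that overlapped a replicate 2 region by at least 1 bp. Chance was estimated from 1000 circular shifts of replicate 2 along each chromosome. Summit locations were compared with 1000 circular shifts in the same way, in the order gene start window, coding exon, UTR, intron, between genes. These locations were defined by protein-coding genes alone, so introns and the regions between genes can hold non-coding genes. The X chromosome share was tested with a two-sided exact binomial test against the X share of nuclear sequence. The RUNX core TGYGGT and every word of 6 bases, merged with its reverse complement to 2080 words, were scored as present or absent within 50 bp of the summit and in a window of the same width centred 300 bp away on a randomly chosen side. The paired presence was tested with an exact McNemar test. Signals of peaks with and without the core were compared by permuting 100000 times. The 23 gene lists and the 94 classes of gene symbols with at least 20 members were tested with two-sided Fisher's exact tests against all other protein-coding genes. P-values called adjusted were adjusted by the Benjamini-Hochberg method within their family, which was the words, the gene lists, the gene classes, the locations, the kinds of non-coding gene or the comparisons of words by place. Other p-values, those of the motif forms included, are not adjusted. The threshold was 0.05. Peaks and genes are not independent replicates, so these p-values describe these lists and not the spread between animals or cultures.

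The lists, their tests and the windows were fixed before the data were examined, as were the tests of replicate overlap, gene starts, the X share, the RUNX core, the words and the signal at core peaks. The comparison of locations other than gene starts and the tests that the closing part names as such were chosen later. In the lists, 1 symbol was not found in the annotation and 1 was matched through its older symbol. Named genes were chosen by a rule fixed at the same time. They are the genes at the start windows of the 15 IDR peaks with the highest signal, or the nearest start where there was none; up to 4 bound members with the highest signal in each list; rnt-1, bro-1, cki-1 and unc-119 in every case; and the 3 highest and 3 lowest gene classes, taken by p-value. Genes named outside this rule are marked as such where they appear.

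Alternatives were other overlap rules and numbers of top regions, start windows of 500 bp to 100 bp and 2000 bp to 500 bp, the 965 IDR peaks with the highest signal, the top 1931 regions of each replicate's own list in place of the IDR list, windows within 25 or 100 bp of the summit, other flanks, other forms of the motif, assignment of each peak to the nearest start within 2000 bp, and permutation of list and class membership 10000 times within deciles of the distance to the next gene upstream. Leaving out peaks within 50 kb of rnt-1 was also planned. Under another window, assignment or peak set the share of other genes changes too. A list was then tested against that share, which is not given here, and not against the main one. Mitochondrial regions were dropped from these sets before each test other than replicate overlap. Those tests therefore used slightly fewer peaks where such regions were present.

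The procedures were tested on simulated data before use. Over 100 draws of 1923 randomly placed peaks, p fell below 0.05 in 3 draws for replicate overlap, 4 for the gene start share and 5 for the RUNX core. Randomly placed peaks lack the higher G+C content of the real summit windows, 49.3% against 35.7% in the flanks. The rate for the RUNX core therefore does not cover that difference. For 1923 simulated peaks with the core written into 9.20% of summit windows, the paired difference came out at 9.78 percentage points. In the scans over 19973 genes, both simulated lists and all 5 simulated classes raised to 35 percent were recovered, and random genes gave 0 calls in either scan. Each simulated gene was bound independently in a single draw, so this does not cover summits shared by neighbouring genes. Shares raised by less were not simulated. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

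One gene that the naming rule selects, from the epidermal junction and attachment list, is counted in the results but is not reported here.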

Results

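RNT-1 is the only RUNX transcription factor of Caenorhabditis elegans and is known for its role in the divisions of the seam cells, the stem-like cells of the epidermis. The series measured where tagged RNT-1 was found on chromatin in late embryos, in 2 biological replicates of 1 group. The list of replicate 1 held 18427 regions, that of replicate 2 held 21390, and that called on both together held 19793, background regions included. The IDR list on ce11 held 1931 peaks with a median width of 436 bp, of which 1923 were nuclear and 8 mitochondrial. These were the 1931 regions with the highest signal of the pooled list, down to a signal of 95.8. The IDR list on ce10 held 2450 peaks and reached down to a signal of 83.9.

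The highest peak lay on chromosome III from 8043739 to 8044159, 531 bp upstream of K12H4.5, with an authors' signal of 1809. M01F1.9, also on chromosome III, followed with 1020. Next came ain-1, a GW182-type component of the microRNA silencing complex, with a summit 967 bp upstream of its start on chromosome X at a signal of 923, and ftt-2, a 14-3-3 protein, at 776. A peak shared by the divergent genes K01G5.10 and tasp-1 had 709, and rpl-3, a protein of the large ribosomal subunit, had 699. The epidermal GATA factor gene elt-1 carried the eighth peak, on chromosome IV from 9615499 to 9615901, with a signal of 605 and its summit 303 bp upstream of the start. The ubiquitin ligase gene eel-1 had 602. Shared start regions followed at atx-2 and ecps-1 with 589, at ears-2 and uncp-18 with 561, at hsr-9 and rps-19 with 543, and at W03C9.5, mex-1 and rab-7 with 541. Of the 15 highest peaks, those nearest to cmd-1, the calmodulin gene, and to Y17G7B.17 lay between protein-coding genes, 4776 bp and 2595 bp upstream of these starts. The seventh lay in the mitochondrial gene ND5.

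The replicates shared most of their strongest regions. The 3 highest peaks, at K12H4.5, M01F1.9 and ain-1, held ranks 1, 2 and 3 in both replicates. The elt-1 peak ranked 7 in replicate 1 and 18 in replicate 2, and rpl-3 ranked 6 in both. Of the 1931 strongest regions of replicate 1, 1438 overlapped one of the 1931 strongest of replicate 2, or 74.5% (95% Wilson interval 72.5 to 76.4). Shifted lists gave 1.64% on average and at most 2.59% (one-sided permutation p = 0.000999, the smallest that 1000 shifts can give). Shifts do not keep the concentration of regions at gene starts described below. The test therefore does not separate shared RNT-1 sites from regions that share only that preference. Across the 1922 IDR peaks with a region in both replicates, signals had a Spearman correlation of 0.644 and a Pearson r of 0.716 on log2 values. This correlation is across peaks, which are not independent replicates and were selected on the pooled signal. Every IDR peak overlapped a region of replicate 1, and 9 overlapped none of replicate 2, of which 8 were mitochondrial.

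**Figure D1:**
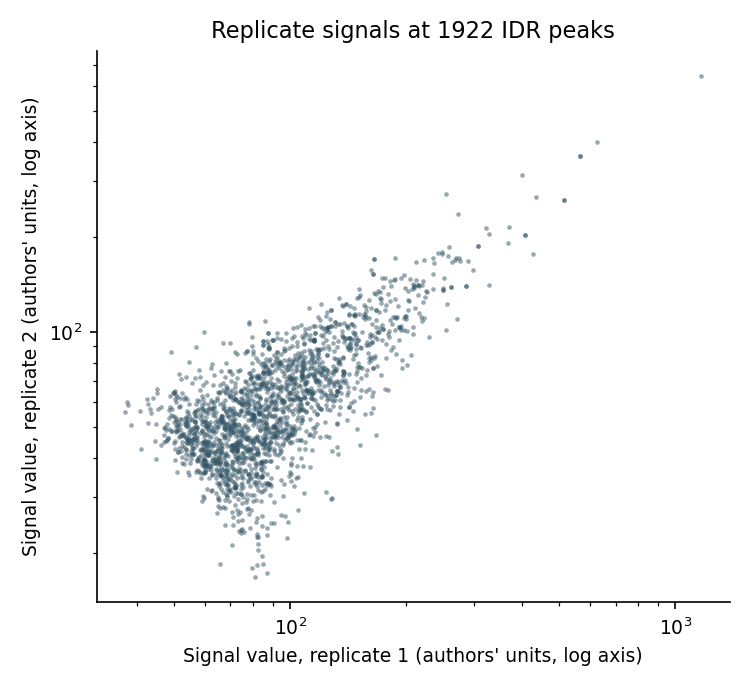
Authors' signal value of each IDR peak in replicate 1 (x axis, log scale) against replicate 2 (y axis, log scale), 1 point per peak, for the 1922 peaks with a region in both lists. The points rise together with a Spearman correlation of 0.644, and the peak at K12H4.5 is highest in both at 1166 and 645.

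Peaks concentrated upstream of genes. Of 1923 nuclear summits, 1061 lay in a gene start window, 55.2% against 25.5% for shifted summits (two-sided permutation p = 0.00200, the smallest that 1000 shifts can give). Coding exons outside these windows held 9 summits, 0.468% against 18.9%, and UTRs held 17, 0.884% against 2.72% (adjusted permutation p = 0.00250 for each, over 5 locations). The coding exon share was 0.938% without replicate 2 and 1.09% without replicate 1. Introns held 320 summits, 16.6% against 27.7%, with the same adjusted permutation p of 0.00250. The regions between protein-coding genes held 516, 26.8% against 25.12%, a difference within the range of the shifts (adjusted permutation p = 0.112). Non-coding genes were not set apart in this comparison. Of the 862 summits outside protein-coding start windows, 472 were also outside the start windows of all other annotated genes. The median summit lay 646 bp from the nearest start. In total 1349 of 19973 protein-coding genes, 6.75%, had a summit at the start, and 318 summits lay at the starts of 2 or more genes.

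**Figure D2:**
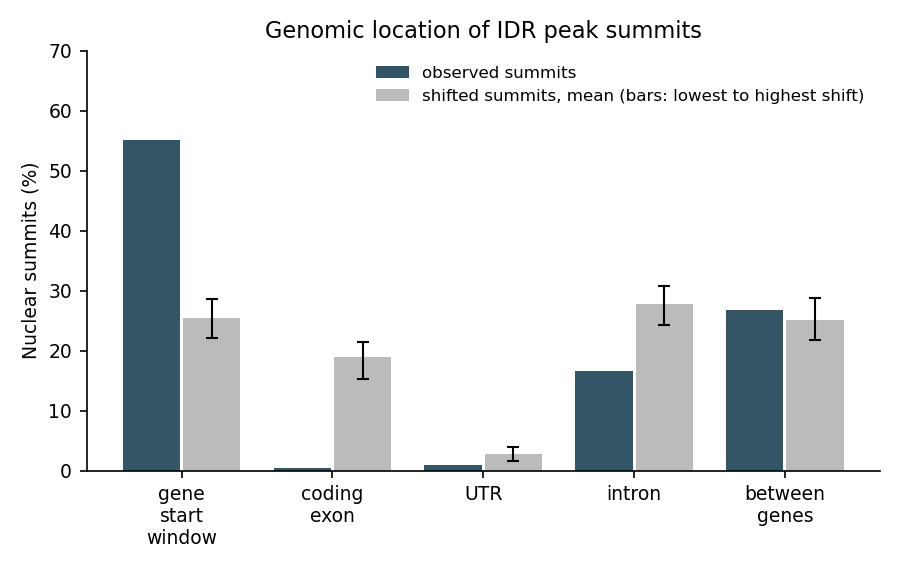
Share of the 1923 nuclear IDR summits (y axis, percent) in each kind of location (x axis), observed and as the mean of 1000 circular shifts, with error bars from the lowest to the highest shift. The gene start window holds 55.2% of observed summits against 25.5% of shifted ones, and coding exons 0.468% against 18.9%. Locations were defined by protein-coding genes alone.

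The X chromosome carried more peaks than its length would give. It held 442 of 1923 nuclear summits, 22.98% (95% exact interval 21.1 to 24.9), against 17.7% of nuclear sequence (two-sided exact binomial p = 3.59e-09). Density was 24.9 peaks per Mb on X, 22.8 on III, 22.3 on I, 19 on II, 15.6 on IV and 12.8 on V. Among the 15 highest peaks, those at ain-1 and ftt-2 were on X. Many of the summits at tRNA genes, described in the closing part, were also on X. Their contribution to the X share was not tested.

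The RUNX core TGYGGT, the sequence that RUNX domains recognize, was more frequent at summits than beside them. It occurred within 50 bp of 285 of 1923 summits, 14.8%, and in 95 flank windows, 4.94% (exact McNemar p = 6.35e-25, with 272 peaks holding it only at the summit and 82 only in the flank). TGCGGT was at 6.97% of summits and 1.46% of flanks, and TGTGGT at 8.42% and 3.59%. The longer form TGTGGTT was found at 1.77% of summits and 0.988% of flanks, which did not pass the threshold (exact McNemar p = 0.0534). The core was present at ain-1, ftt-2 and rps-19 and absent within 50 bp of the summits at K12H4.5, M01F1.9, rpl-3 and elt-1. Most summits, 1638, had no core within 50 bp.

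Other words passed the test with smaller p-values than the core words. GAGAGA occurred at 29.7% of summits and 6.92% of flanks, and ACGCAG at 14.2% against 1.87% (adjusted p = 1.88e-74 and 1.66e-46, exact McNemar tests adjusted over all words of 6 bases). The A-rich word AAAAAT was at 15.5% of summits and 47.2% of flanks. In all, 732 words were more frequent and 518 less frequent at summits. ACCGCA and ACCACA, which are the core words read on the other strand, ranked 65 and 182 by p-value among the more frequent ones. Summit windows had a G+C content of 49.3% and flank windows 35.7%.

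**Figure D3:**
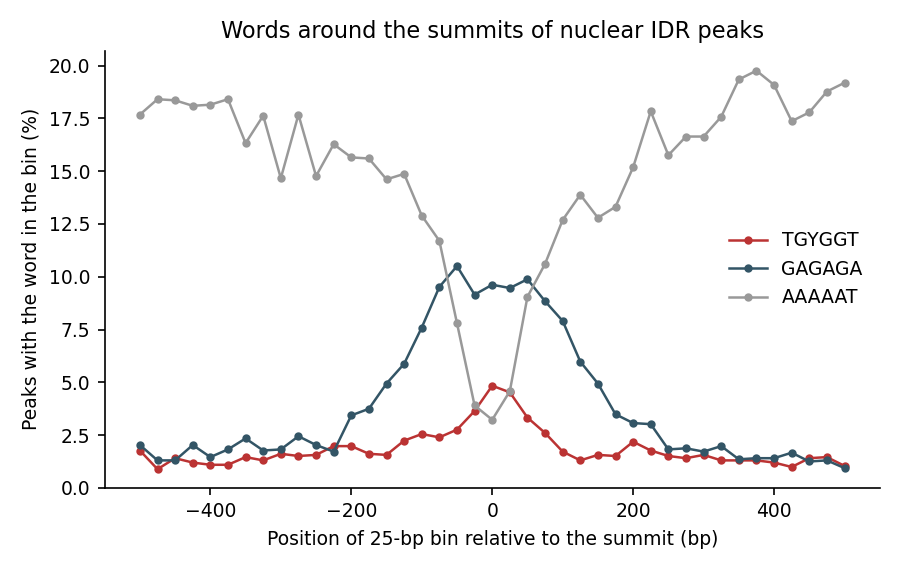
Share of the 1923 nuclear IDR peaks with a word in each 25-bp bin (y axis, percent) by distance from the summit (x axis, bp), 1 line per word. TGYGGT is highest in the bin at the summit, at 4.84%, while GAGAGA stays between 8.84% and 10.5% from 75 bp before to 75 bp after it and AAAAAT dips.

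Peaks with the core were not detectably stronger. Their median signal was 141 (interquartile range 114 to 197, 285 peaks) against 137 (112.2 to 181, 1638 peaks) for those without it (two-sided permutation p = 0.247). The core was at 19.2% of the 385 strongest peaks (95% Wilson interval 15.6 to 23.5) and at 12.8% of the 384 weakest (9.79 to 16.47). Among the 965 peaks with the highest signal alone, the medians differed by 9.77 (permutation p = 0.0395). The top regions of replicate 1 alone gave a difference of -1.49 (permutation p = 0.528).

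Genes of muscle and of protein synthesis and folding stood out among the gene lists. Of 30 body wall muscle genes, 16 had a summit at the start, 53.3% against 6.68% of other genes (Fisher's exact test, adjusted p = 7.76e-11). They included unc-112, a kindlin of the muscle attachment sites, with a signal of 279, the major myosin heavy chain gene unc-54 with 267, the troponin T gene tnt-2 with 252 and dim-1 with 205. Of 76 cytosolic ribosomal protein genes, 37 were bound, 48.7% against 6.59% (adjusted p = 1.81e-22, Fisher's exact test), led by rpl-3 with 699, rps-19 with 543, rpl-15 with 438 and rpl-35 with 432. Heat shock and chaperone genes had 12 of 30 bound, 40% against 6.70% (adjusted p = 1.36e-06, Fisher's exact test), among them the mitochondrial chaperonin hsp-60 with 325, hsp-90 with 287, hsp-1 with 268 and the cytosolic chaperonin subunit cct-7 with 200. With each peak assigned to its nearest start, the ribosomal share was 30.3% and the chaperone share 20% (adjusted p = 4.49e-09 and 0.0249, Fisher's exact test). In this and the other alternatives below, the share of other genes also differs from the main one.

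A further 3 lists passed the threshold with fewer bound members. Of 18 heterochronic genes, which time larval cell fates, 6 were bound, 33.3% against 6.73% (adjusted p = 0.00330, Fisher's exact test), namely ain-1 with 923, nhl-2 with 381, lin-28 with 149, lin-14 with 122 and also nhr-23 and alg-1. Of 13 Hox genes and cofactors, 5 were bound, 38.5% against 6.73% (adjusted p = 0.00373, Fisher's exact test). These were the Polycomb-like genes sor-1 with 144 and sop-2 with 99.6, the cofactor ceh-20 with 125, and the Hox genes lin-39 with 103 and ceh-13. Of 28 genes of epidermal junctions and attachment, 6 were bound, 21.4% against 6.73% (adjusted p = 0.0281, Fisher's exact test), with the alpha spectrin gene spc-1 at 237, the spectraplakin vab-10 at 121 and the beta spectrin unc-70 at 114 among them. These 3 lists were no longer called with start windows of 500 bp to 100 bp or among the 965 strongest peaks. Without replicate 2 the heterochronic share was 22.2% (adjusted p = 0.0800, Fisher's exact test). Without replicate 1 the Hox share was 15.4% and the epidermal share 7.14% (adjusted p = 0.434 and 0.958, Fisher's exact test). Members beyond the fourth in each list were named after their values were seen.

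The seam and epidermal regulators had 4 of 26 bound, 15.4%, which did not pass the threshold (Fisher's exact test, adjusted p = 0.198). They were elt-1 with 605, tlp-1 with 228, ceh-20 with 125 and nhr-23 with 103. With start windows of 2000 bp to 500 bp the share was 26.9%, and the same with each peak assigned to its nearest start (adjusted p = 0.0154 and 0.00394, Fisher's exact test). It was 7.69% with windows of 500 bp to 100 bp and among the 965 strongest peaks (adjusted p = 0.732 and 0.575, Fisher's exact test). Ras and EGF signalling had 5 of 25 bound (adjusted p = 0.0610, Fisher's exact test), with egl-17, a fibroblast growth factor gene, at 330, gap-3 at 155, gap-2 at 112.4 and eor-2 at 106. Cuticle structure and moulting had 6 of 40, with lpr-3 at 184, dpy-14 at 124, cut-2 at 117 and noah-1 at 114.99 (adjusted p = 0.116, Fisher's exact test). The cuticle share was 20% with nearest starts (adjusted p = 0.0111, Fisher's exact test), 5% without replicate 1 and 2.5% among the 965 strongest peaks. Wnt signalling had 4 of 29, with vang-1 at 272, mom-1 at 187, mig-5 at 170 and lit-1 at 122, and Notch signalling 3 of 22, with adm-4 at 111.6, apx-1 at 103 and sel-10 at 102 (adjusted p = 0.247 and 0.280, Fisher's exact test). The egl-17 and mom-1 peaks also lay at the starts of tRNA genes, and the mig-5 peak at that of a chaperone gene. Which of the genes such a peak belongs to cannot be told from its position. With the windows of 2000 bp to 500 bp, Wnt signalling reached 34.5% and Ras and EGF signalling 28% (adjusted p = 0.000607 and 0.0134, Fisher's exact test). Nearest starts gave 31.03% and 24% (adjusted p = 0.000360 and 0.0117, Fisher's exact test). Windows of 500 bp to 100 bp gave 6.90% and 12% (adjusted p = 0.757 and 0.382, Fisher's exact test). The Ras and EGF share was 8% among the strongest peaks and 12% without replicate 1, and the Wnt share 10.3% among the strongest peaks. The Notch share was 4.55% without replicate 1.

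The cell cycle list had 4 of 39 bound, efl-1 at 191, fzr-1 at 191, cdc-14 at 123 and lin-23 at 113 (adjusted p = 0.451, Fisher's exact test). Genes of general neuronal function had 3 of 26, unc-76 at 244, maco-1 at 161 and unc-108 at 143 (adjusted p = 0.367, exact). Axon guidance and cell migration had 3 of 34, unc-115 at 186, let-2 at 140 and smp-1 at 122 (adjusted p = 0.603, exact), and reached 20.6% with each peak assigned to its nearest start (adjusted p = 0.0133, exact). The axon guidance share was 14.7% without replicate 2, and 5.88% with windows of 500 bp to 100 bp and among the strongest peaks. Stress MAPK signalling had 2 of 21, kgb-1 at 197 and mek-1 at 124 (adjusted p = 0.747, exact), germline 2 of 47, mex-1 at 541 and cgh-1 at 167 (adjusted p = 0.843, exact), and TGF-beta signalling 1 of 21, sma-9 at 126 (adjusted p = 1, exact).

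No bound gene was found among 35 intestinal genes, 33 neuronal fate regulators or 26 pharyngeal genes. The upper ends of the 95% Wilson intervals were 9.89%, 10.4% and 12.9%, all above the 6.75% of protein-coding genes, and none passed the test (adjusted p = 0.280, 0.280 and 0.533, Fisher's exact test). The pharyngeal share was 3.85% without replicate 1, and that of neuronal fate regulators 3.03% with windows of 2000 bp to 500 bp and with nearest starts. Chemoreceptor genes had 9 of 1309 bound, 0.688% against 7.18% of other genes (adjusted p = 8.78e-28, Fisher's exact test). The F-box families had 5 of 322, 1.55% against 6.84% (adjusted p = 0.000114, Fisher's exact test). Of the 23 lists, 6 were higher and 2 lower, and permuting membership within deciles of upstream distance called the same 6 higher.

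**Figure D4:**
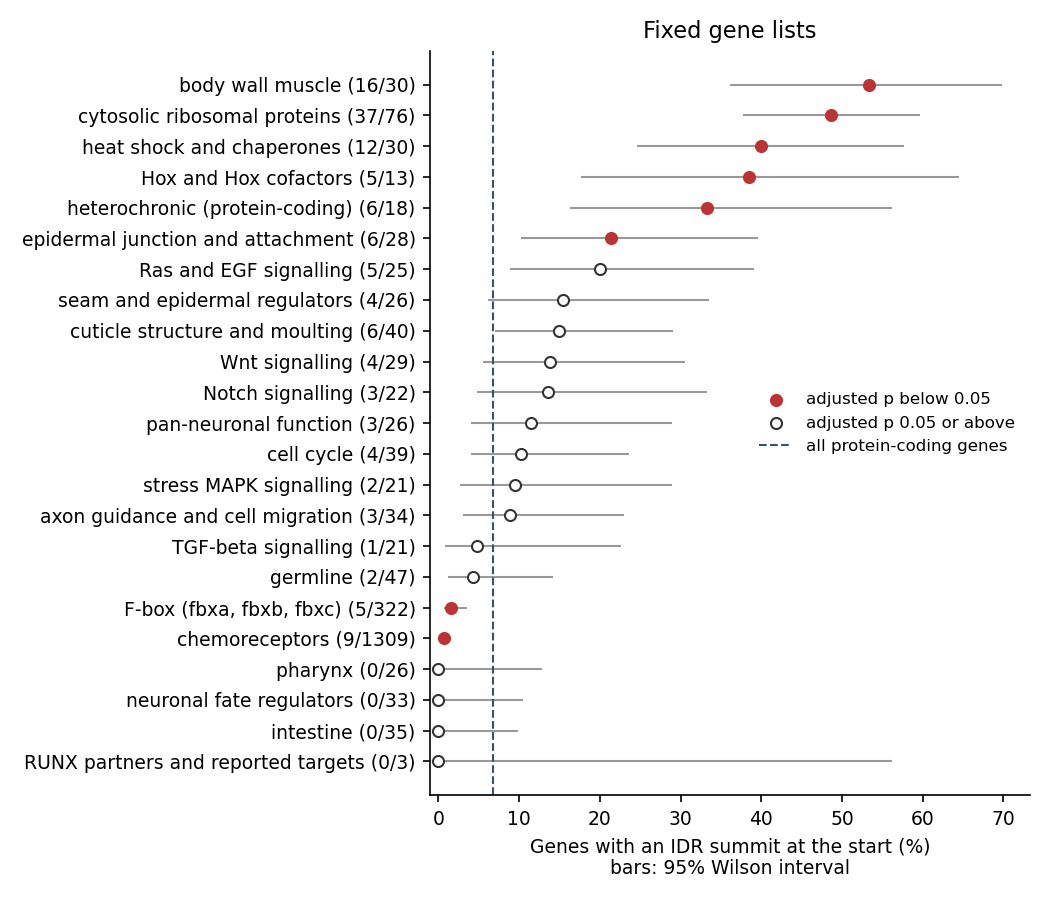
Share of the members of each of the 23 gene lists with an IDR summit at the start (x axis, percent), with 95% Wilson intervals, filled where the adjusted p of Fisher's exact test was below 0.05. Body wall muscle (53.3%), ribosomal proteins (48.7%) and chaperones (40%) lie farthest above the 6.75% of all protein-coding genes, drawn as a dashed line.

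A scan of 94 gene classes, read from gene symbols without regard to function, gave the ribosomal classes the smallest p-values. The rpl class had 23 of 47 genes bound, 48.9%, and rps 16 of 31, 51.6% (adjusted p = 3.15e-13 and 9.22e-10, Fisher's exact test). The unc class, named for uncoordinated movement, had 21 of 94, 22.3% (adjusted p = 2.88e-05, Fisher's exact test). The rpl and rps classes share members with the ribosomal list, and the unc class with the muscle list. Their results are therefore not independent of those lists. Of the classes with a lower share, those with the smallest p-values were the chemoreceptor class str with 0 of 193, the C-type lectin class clec with 3 of 240 and the chemoreceptor class srw with 0 of 109 (adjusted p = 4.68e-05, 0.00111 and 0.00980, Fisher's exact test). The srw class did not pass with windows of 500 bp to 100 bp or among the 965 strongest peaks, with 0 bound in both (adjusted p = 0.0593 and 0.199, Fisher's exact test). In all, 7 classes were higher and 6 lower, and 5 and 6 with permutation within deciles. The number lower was 3 with windows of 500 bp to 100 bp, 12 with windows of 2000 bp to 500 bp and 2 among the strongest peaks. The top regions of replicate 1 alone called 12 classes higher and those of replicate 2 alone 11.

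The gene of the tagged protein and its named partners had no IDR summit at their starts. rnt-1, on chromosome I from 5776093 to 5788611, had no region of the pooled list in its start window, and the nearest IDR summit was 69094 bp away. bro-1, which encodes the CBF-beta partner of RNT-1, had a pooled region with a signal of 33.8, rank 15036. cki-1, a cyclin-dependent kinase inhibitor gene reported as a RUNX target in the worm, had one with 73.1, rank 3096. unc-119, the gene mutated in the background of the strain, had one with 30.3, rank 18755. All these lay below the lowest IDR signal of 95.8. With 0 of 3, the list of rnt-1, bro-1 and cki-1 is too short to pass the test in that direction.

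**Figure D5:**
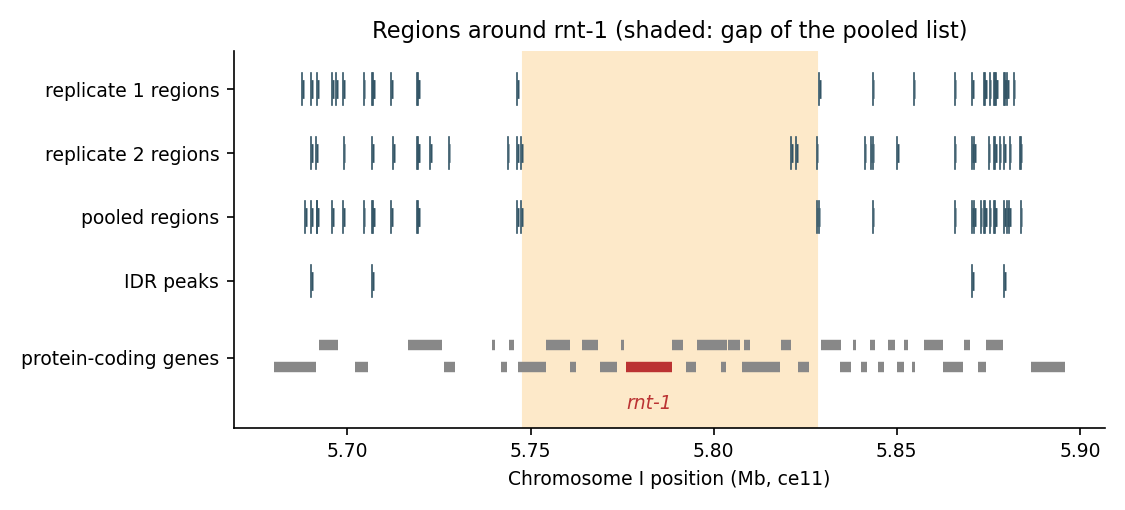
Regions of the replicate, pooled and IDR lists (blue marks) and protein-coding genes (grey, rnt-1 in red) along chromosome I (x axis, Mb, ce11). The shaded stretch of 80236 bp holds no region of the pooled list, and replicate 2 has 2 regions inside it.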

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

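The mitochondrial regions enter none of the nuclear comparisons and were listed because their number exceeded 3, the floor set for counts. Replicate 1 had 14 mitochondrial regions and replicate 2 had 0. The pooled list had 9 and the IDR list 8. The strongest of these lay in ND5 from 12214 to 12649 with a signal of 608, and others lay in COX1 with 329, COX3 with 328 and CYTB with 293, genes named after their values were seen. No technical or biological explanation for them was tested.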

How the results depend on the processing

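Of 52 alternative values for the main results, 44 kept their direction and their side of the threshold or stayed within 1.5 times. These cover replicate overlap (66.9% to 74.8%), the gene start share (43.2% to 69.6%), the X share, the RUNX core and the 6-mer scan (578 to 791 words), apart from the motif form TGTGGTT, whose difference of 0.780 points did not pass. The number of lists called higher fell from 6 to 3 with start windows of 500 bp to 100 bp and to 3 among the 965 strongest peaks, and was 11 with each peak assigned to its nearest start. Classes called higher numbered 11 to 12 without either replicate against 7, and hsp, mdt, vha, gly and rab, named after their values were seen, were gained in both cases. The signal difference at core peaks passed the threshold among the strongest peaks, at 9.77. It was -1.49 without replicate 2 and 3.59 without replicate 1, in lists whose signal values differ in size. The causes were not tested. Of 678 alternative values for single lists, classes, words, locations and genes, 555 were likewise unchanged.

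Direction changed for lists with few bound members. Direction is relative to the share of other genes in the same setting, which changes with the peak set and the window. Among the strongest peaks, shares were 3.57% for epidermal junctions, 2.5% for cuticle, 4.26% for germline and 0 for Notch. The germline share was also 4.26% in the main result, so for this list only the comparison share moved. Without either replicate, cuticle ranged from 5% to 15% and Notch from 4.55% to 13.6%. TGF-beta signalling reached 9.52% with the 2000 bp window and with nearest starts, and stress MAPK signalling fell to 0 with the 500 bp window. The share between protein-coding genes was 24.4% among the strongest peaks, an alternative chosen after seeing the data, like those for the other locations and for non-coding genes. Of the 70 bound genes that the naming rule selects, 39 were bound with the 500 bp window, 48 among the strongest peaks, 67 without replicate 2 and 59 without replicate 1. Leaving out peaks within 50 kb of rnt-1 removed 0 peaks, tests nothing and is not counted here. Replicate overlap has no value without a replicate. Depth is unknown, so weak binding cannot be bounded.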

Other observations

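The tests of non-coding genes, of core and GAGAGA words by place, of the core outside the starts of all annotated genes, of the gap around rnt-1 and the bootstrap below were chosen after the main results were seen. The genes named here other than rnt-1 were chosen after their values were seen.

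Genes of tRNAs and snoRNAs had summits at their starts far more often than shifted summits gave. Of 612 tRNA genes, 157 had an IDR summit at the start, 25.7%, where shifted summits gave 14.9 genes on average and at most 29. Of 346 snoRNA genes, 84 were bound, 24.3%, against 7.82 genes for shifted summits and at most 18 (adjusted permutation p = 0.00225 for both, over 9 kinds of non-coding gene, from the smallest p that 1000 shifts can give). The tRNA genes were reached by 142 summits, 107 of them outside the start windows of protein-coding genes. The snoRNA genes were reached by 81 summits, of which 41 were outside these windows and 7 lay at the starts of ribosomal protein genes. With only the summits outside these windows, 19.4% of tRNA genes and 12.1% of snoRNA genes (42 genes) were bound, where shifted summits gave 11.5 and 5.40 genes on average (adjusted permutation p = 0.00200 for both, over 3 kinds of gene, the smallest that 1000 shifts can give). The snoRNA genes C51F7.3 and C51F7.4 shared the peak of rank 17 with a signal of 471. Summits near snoRNA genes made up 9.64% of the 384 strongest peaks and 1.82% of the 384 weakest, and 5.21% and 0.521% when only those outside the windows were counted. The tRNA share was 20.8% without replicate 1 and 26.5% without replicate 2. The core TGYGGT was at 20.4% of tRNA summits against 14.4% of other summits. For snoRNA summits it was at 19.8% against 14.6% (adjusted p = 0.420 for both, Fisher's exact test). Whether signal at strongly transcribed or open starts accounts for these summits was not tested, since control data were not analysed here.

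MicroRNA genes had 36 of 261 bound, 13.8%, against 6.29 genes for shifted summits (adjusted permutation p = 0.00225). These genes were reached by 25 summits, since clustered genes share a peak, and 17 of the summits lay outside protein-coding start windows. With only the summits outside these windows, 28 microRNA genes were bound, against 4.83 for shifted summits (adjusted permutation p = 0.00200). The cluster from cel-mir-35 to cel-mir-40, a family known from embryos, lay at 1 peak with a signal of 138, and the muscle microRNA gene cel-mir-1 had 128. The clustered genes cel-mir-54, cel-mir-55 and cel-mir-56 on X shared a peak of 288, and cel-mir-51 had 322. Pseudogenes and piRNA genes were below shifted summits, with 19 of 2128 and 149 of 15363 (adjusted permutation p = 0.00225 for both). Of the remaining kinds, snRNA genes (11 genes, 8.53%), lincRNA genes (14 of 194) and other ncRNA genes (652 of 7764) were above shifted summits with the same adjusted p, and antisense RNA genes (4 of 100) did not pass (adjusted permutation p = 0.298). Shifted summits do not keep the concentration at protein-coding starts. Outside those windows lay 6 of 14 lincRNA summits, 5 of 12 snRNA summits and 283 of 497 other ncRNA summits. These kinds were not tested with such summits alone. Some ncRNA genes also overlap a tRNA or snoRNA gene at the same peak, so the kinds are not separate results.

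The core TGYGGT was at 19.7% of summits on X and 13.4% on autosomes (Fisher's exact test, adjusted p = 0.00269 over 4 comparisons). GAGAGA was at 28.1% on X and 30.2% on autosomes (adjusted p = 0.407, Fisher's exact test) and was less frequent at gene starts, 26.4%, than elsewhere, 33.9% (adjusted p = 0.00148, Fisher's exact test).

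The excess of the RUNX core at summits was set against the other features of these windows. Among the 862 peaks outside the starts of protein-coding genes the core was 11.4 points more frequent at the summit than in the flank (exact McNemar p = 1.78e-14). Among the 472 peaks outside the starts of all annotated genes, non-coding ones included, it was 9.75 points more frequent (exact McNemar p = 3.32e-07). Both argue against a sequence found within these start windows as the whole cause. Sequence farther from the annotated starts was not removed. Protein-coding start windows of 2000 bp to 500 bp hold 69.6% of summits, against 55.2% for the windows used. Against words with as many G and C bases, ACCGCA lay at percentile 98.2 and ACCACA at 95.8 for the ratio of summit to flank. The rule set beforehand used these percentiles alone, and the lower of 95.8 was above its bound of 95, which went against base composition. Resampling the peaks, a criterion added later, gave 95% ranges of 89.6 to 99.8 and 84.7 to 98.3. Both reach below that bound, so base composition and sequence-specific binding cannot be told apart by this test. No biological explanation was tested, as the design has 1 group.

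Peaks at ribosomal protein and body wall muscle genes may reflect signal at strongly transcribed or open starts rather than RUNX sites. The core was at 11.1% of 36 ribosomal gene peaks and at 11.1% of 18 muscle gene peaks. Other gene start peaks had it at 13.9% and 13.8% (Fisher's exact p = 0.808 and 1). The muscle set is too small for a lower share to pass, since its smallest possible p is 0.157, and for both sets the explanations cannot be told apart. Control data were not analysed here.

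The stretch without any pooled region around rnt-1, from 5747865 to 5828100 on chromosome I, is the longest such gap of that chromosome in the pooled list. The list of replicate 2 has 2 regions inside it, and its own gap around rnt-1, from 5747847 to 5821223, is the longest of that chromosome in that list. The gap of 81985 bp in the list of replicate 1 is also the longest there. Repeats are argued against, since 98.3% of its 31-mers occur once in the genome, while the longest gap of the genome, on V, has 5.16%. A lack of genes is too, since it holds 17 gene midpoints, among them lin-35 and hmg-3, at percentile 56.1 of windows of its length. Gaps as long or longer hold 1.2% of protein-coding genes. The length of the gap is what drew attention to it, so this share does not exclude chance, and chance and another cause cannot be told apart. Extra copies of the locus in the tagged strain, which would raise control coverage over the stretch, stay open as a hypothesis and were not tested, since control data were not analysed here.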
